A study of Mus musculus with 12 samples.

How the data were processed

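Bulk RNA was sequenced from mouse leukemia cells that carry the MLL::AF9 fusion, came from bone marrow and were enriched for stem cells. The cells had received a control guide RNA or 1 of 2 guide RNAs against Glut1, the glucose transporter encoded by Slc2a1, and GFP-positive cells were sorted 3 days after transduction. The 12 libraries fall into 3 groups of 4: control, guide 1 and guide 2. Per the labels, RNA came from a PicoPure kit and libraries from a TruSeq RNA kit. The columns of the table were matched to samples by the sample descriptions, and 0 columns with values per library were left unused.

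The deposited table holds FPKM (fragments scaled to transcript length and to the mapped fragments of the library) made by the authors, for 24350 rows named by gene symbol. The submitters' processing notes name bcl2fastq, STAR 2.5.0a and Cufflinks and the builds GRCm38 and mm10, without their settings. The FPKM totals per library ran from 590561 to 643260 in control and from 643432 to 737648 with the guides, and no scaling was added. Read counts were not analysed here, so the absolute depth of each library is unknown and no counting interval is given. The replicate spread sets the precision. The deposited p-value column equals a two-sample test on linear FPKM within 1% for 100% of 10635 genes, and it was not used. The authors' column headed as a fold change equals 2 to the power of a difference of mean FPKM within 0.01 on the log2 scale for 100% of 24340 finite rows. It was not read as a fold change. The table has 27 symbols turned into dates and 4 rows with a duplicated symbol, which were counted but not named. It lists 0 mitochondrial genes. Coordinates come from a GENCODE annotation of GRCm38, the build in the submitters' notes, which holds 96% of the tested symbols.

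Values were log2(FPKM + 1), for the 10635 genes with a mean FPKM of at least 1 over the 12 libraries. All log2 changes and the fold minimum of 2 are on this scale, which shrinks the FPKM ratio of genes with low values. The trend method of limma 3.58.1 in R 4.3.3 was fitted once to the 3 groups, with 4 contrasts: both guides averaged against control, each guide against control, and guide 2 against guide 1. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. All tests are two-sided. They measure the spread between these samples, since the labels do not say that replicates are separate cultures. Slc2a1 and Slc2a3 were also tested by exact permutation of the libraries, for which the smallest possible p is 0.029 with 70 arrangements for a single guide and 0.002 with 495 for both.

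There were 44 gene lists, of which 41 had at least 5 tested genes, with Slc2a1 left out of each. They were tested by camera (limma) with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were the alternatives. Genes called with both guides were counted by direction, beside the number that 100 simulated draws with no effect and shared controls gave, and beside the overlap of independent lists.

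The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Slc2a1 and 10 single genes. For both guides averaged it takes the 12 largest increases and 12 largest decreases with a mean of at least 5 FPKM in the higher group and all 8 guide libraries on 1 side of the control mean. It takes the 5 largest each way in the other contrasts, up to 4 members of each list called in the averaged contrast and up to 2 of each chosen energy list, by adjusted p. Predicted genes, pseudogenes and duplicated symbols are not named.

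The fit was tested on simulated data with 10477 genes. Changes of each size were put into 66 or 67 genes, alike for both guides, with independent noise. The changed genes were raised to a minimum expression first, so recovery among genes of low expression was not measured. Libraries that stand apart from their group were not simulated either. For both guides averaged it recovered 84.8% of changes of 0.5, 95.5% of changes of 1 and 98.5% of changes of 2 on the log2 scale, with 2.62% false calls. For guide 1 these were 77.3%, 95.5%, 98.5% and 4.23%, and for guide 2 they were 78.8%, 95.5%, 98.5% and 4.21%.

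The alternatives were a pseudocount of 0.1 or 0.5, no filter, a minimum mean of 5 FPKM, median-ratio scaling, quantile normalization, limma without the trend or with robust hyperparameters, array weights, a replicate block (the replicate number as a factor), only the 2 groups compared, a fold minimum of 2, control libraries split between the guides, and each library left out in turn. A covariate was added after seeing the data: each library's projection on the difference between control replicates 1 and 2 and control replicates 3 and 4. A first coding of it as 0 or 1 was tried and dropped, since it sorted the libraries by a measured outcome. The covariate is also computed from the expression values it is fitted to, so no conclusion rests on it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.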

Results

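Gene expression was measured in 12 libraries of sorted mouse MLL::AF9 leukemia cells, 4 with a control guide RNA, 4 with Glut1 guide 1 and 4 with Glut1 guide 2. Between 13885 and 15732 genes had a value above 0 in a library. Correlations of log2 values across genes, which are not independent replicates, ran from 0.9784 to 0.9926 within groups. Guide 2 replicate 4 stood apart from its group: it correlated at 0.9841 to 0.9898 with guide 1 and at 0.9784 to 0.9804 with guide 2 replicates 1 to 3.

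The first question was whether the transcript of the targeted gene changed. Slc2a1, the gene of the glucose transporter Glut1 (chromosome 4, 119108711 to 119137983 in GRCm38, overlapping an exon of Gm12868), had 53.03 ± 12.7 FPKM in control, 35.9 ± 2.62 with guide 1 and 58.1 ± 9.55 with guide 2 (SD, n = 4). Its log2 change was -0.52 with guide 1 (limma adjusted p = 0.019, exact permutation p = 0.057). It was 0.15 with guide 2 (limma adjusted p = 0.52, exact permutation p = 0.57) and -0.19 for both guides averaged (limma adjusted p = 0.30, exact permutation p = 0.43). The guides differed by 0.67 (limma adjusted p = 0.029, exact permutation p = 0.029, the smallest it can give). The guide 1 call ended without control replicate 1 (-0.42, adjusted p = 0.06) or control replicate 2 (-0.44, adjusted p = 0.058), and without control replicate 3 the average was called (-0.35, adjusted p = 0.03) and guide 2 was at -0.02. The guide difference was lost without guide 1 replicate 1, 2 or 4 or guide 2 replicate 1, 2 or 3 (adjusted p = 0.07 to 0.093). Transcript level does not measure the edit or the protein, which were not analysed here.

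**Figure D1:**
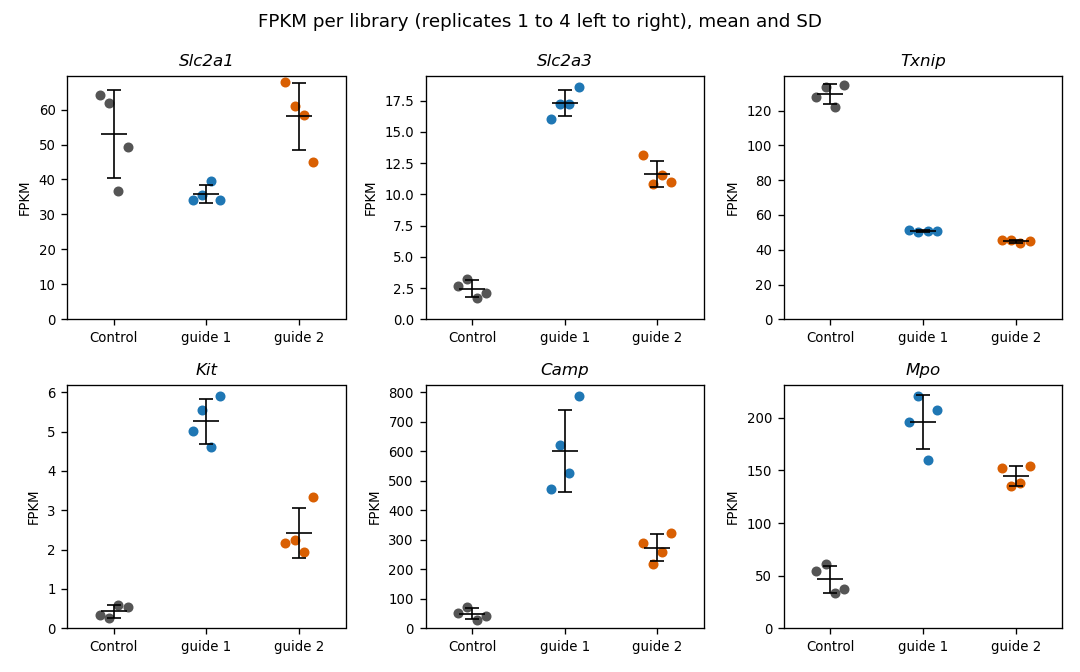
FPKM per library for 6 genes, with replicates 1 to 4 of each group from left to right and the mean and SD as bars, on axes that start at 0. Slc2a3, Kit, Camp and Mpo lie above all control libraries in every guide library and Txnip below them, while Slc2a1 overlaps between control and both guides.

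Both guides averaged against control tested what the guides changed on average. Slc2a3, the gene of another glucose transporter, rose from 2.44 ± 0.681 FPKM in control to 17.3 ± 1.05 with guide 1 and 11.6 ± 1.07 with guide 2 (SD, n = 4), a log2 change of 2.16 (adjusted p = 8.62e-08). Txnip, an arrestin-family gene that responds to glucose, fell from 130 ± 5.75 to 50.6 ± 0.496 and 45.0 ± 0.86 FPKM, a log2 change of -1.42 (adjusted p = 6.91e-11). Its relative Arrdc4 fell by 1.78. Neutrophil granule genes rose: Camp, an antimicrobial peptide, from 49.0 ± 18.9 to 601 ± 138 and 273 ± 44.9 FPKM, and Mpo, myeloperoxidase, from 46.4 ± 13.1 to 196 ± 25.8 and 145 ± 9.77 FPKM. Kit, the receptor of stem cell factor, rose from 0.431 ± 0.156 to 5.26 ± 0.578 and 2.42 ± 0.624 FPKM (log2 change 1.69, adjusted p = 5.64e-07). Over both guides its mean FPKM rose 8.92-fold, more than this log2 change of FPKM + 1 gives.

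In all, 2039 genes were higher and 2216 lower of 10635 tested, and 76 and 38 of these changed at least 2-fold in FPKM + 1. This leaves out some genes whose FPKM changed more than 2-fold, such as Ddit4 (2.11-fold, log2 change 0.96). The 12 largest increases by the rule were Camp (3.08), Fcnb (2.17), Slc2a3, Ngp (2.04), Tmem119 (1.97), Adm2 (1.94), Chil1 (1.92), Ltf (1.91), Mpo (1.87), Cth (1.70), Dusp1 (1.63) and Penk (1.51), as log2 changes. The 12 largest decreases were Gstt1 (-2.70), Hpgd (-1.93), Btla (-1.86), Wfdc15a (-1.79), Arrdc4 (-1.78), Prdx4 (-1.57), Slc18a1 (-1.55), Tespa1 (-1.43), P2rx7 (-1.43), Txnip (-1.42), Ms4a6b (-1.39) and Glra3 (-1.32). On the deposited scale 47.9% of the changed genes were higher, and with median-ratio scaling 51.1%.

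Of the fixed genes, Hk2, a hexokinase of glycolysis, rose from 31.0 ± 1.38 FPKM to 50.1 ± 4.37 over both guides (n = 8), a log2 change of 0.67. Hoxa9 and Meis1, transcription factors of the MLL-fusion program, fell by 0.43 and 0.45. The changes of Myc (0.28, adjusted p = 0.28) and Itgam (0.03, adjusted p = 0.77) did not pass. Cdkn1a, a p53 target, fell by 0.34 (adjusted p = 0.04), a call that ended without 1 of 7 libraries, namely control replicate 1 or 2, guide 1 replicate 1, 2 or 4, or guide 2 replicate 3 or 4 (highest adjusted p = 0.14). Over every library left out in turn its log2 change ran from -0.45 to -0.26.

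The 6 lists that rose covered the amino acid response, hypoxia, granules, immediate-early genes, ribosomal proteins and cholesterol synthesis. Of 37 tested genes of the ATF4-driven amino acid response, 28 were higher and 0 lower (29 and 1 adjusted over the list alone, with a median log2 change of 0.33 and a camera adjusted p = 3e-11). Among them were Cth, Slc6a9 (1.40), Trib3 (1.40) and Atf5 (1.22). Of 25 hypoxia-response genes, 19 were higher and 0 lower (19 and 1 adjusted over the list alone, with a median of 0.31 and an adjusted p = 4.2e-06). Among them were Ddit4 (0.96), Vegfa (0.73), Egln1 (0.54) and Bnip3l (0.37). Of 35 granule genes, 24 were higher and 1 lower (25 and 1 adjusted over the list alone, with a median of 0.44 and an adjusted p = 1.7e-10). Of 20 immediate-early genes, 12 were higher and 1 lower (13 and 1 adjusted over the list alone, with a median of 0.37 and an adjusted p = 0.0011). Zfp36 rose by 0.73 and Egr1 by 0.70. The immediate-early list is often raised by handling, and its mean log2 value was 4.43 and 4.40 in control replicates 1 and 2, 3.93 and 3.94 in control replicates 3 and 4, 4.49 to 4.92 with guide 1, 4.60 to 4.93 in guide 2 replicates 1 to 3 and 4.35 in guide 2 replicate 4. Of 79 cytosolic ribosomal protein genes, 59 were higher and 0 lower (65 and 0 adjusted over the list alone, with a median of 0.25 and an adjusted p = 8.7e-15). Among them were Rpl10 (0.45) and Rps28 (0.39). With quantile normalization 27 were higher and 1 lower, and 24 of the 59 remained, while with median-ratio scaling all 59 remained. Of 24 cholesterol synthesis genes, 8 were higher and 2 lower (8 and 2 adjusted over the list alone, with a median of 0.08 and an adjusted p = 0.048). Fdps was at 0.33. All 10 calls were lost with an estimated correlation, with adjusted p = 0.39 for the amino acid response and granule lists, adjusted p = 0.57 for hypoxia, adjusted p = 0.63 for ribosomal proteins, adjusted p = 0.65 for immediate-early and adjusted p = 0.66 for cholesterol synthesis.

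Glucose-responsive genes had the lowest median of the lists that fell. Of 6 tested genes of the glucose-responsive list, 4 were lower and 1 higher (4 and 1 adjusted over the list alone, with a median of -0.66 and an adjusted p = 0.017, and adjusted p = 0.39 with an estimated correlation). The lower ones were Txnip, Arrdc4, Arrdc3 (-0.80) and Klf10 (-0.53). Of 31 p53 targets, 16 were lower and 4 higher (18 and 6 adjusted over the list alone, with a median of -0.21 and an adjusted p = 0.029, and adjusted p = 0.65 with an estimated correlation). Cd80 was at -1.02 and Ddb2 at 0.53. Of 76 mitochondrial ribosomal genes, 27 were lower and 7 higher (29 and 7 adjusted over the list alone, with a median of -0.09 and an adjusted p = 0.047, and adjusted p = 0.77 with an estimated correlation). Mrpl41 was at -0.42 and Mrpl48 at 0.63. Of 54 lysosome and autophagy genes, 21 were lower and 6 higher (22 and 7 adjusted over the list alone, with a median of -0.11 and an adjusted p = 0.049, and adjusted p = 0.77 with an estimated correlation). Gusb was at -0.50 and Atg12 at 0.41. The mean log2 value of this list was 5.53 in control replicates 1 and 2 and 5.37 and 5.39 in control replicates 3 and 4. It was 5.27 to 5.36 with guide 1, 5.435 to 5.513 in guide 2 replicates 1 to 3 and 5.27 in guide 2 replicate 4. For p53 targets these values were 3.90 and 3.88, 3.72 and 3.76, 3.53 to 3.63, 3.79 to 3.88 and 3.64. The last 3 lists were not called with guide 2 (adjusted p = 0.26, 0.24 and 0.23), and cholesterol synthesis was not called with guide 1 (adjusted p = 0.086). Without guide 2 replicate 4 the last 3 had adjusted p = 0.05, 0.068 and 0.093. With quantile normalization the last 2 had adjusted p = 0.051.

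The energy lists did not pass for both guides averaged. Of 25 glycolysis genes, 8 were higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.051), with Hk2 and Pfkfb4 (0.42) first. The TCA cycle list had 13 of 31 lower and 3 higher (14 and 3 adjusted over the list alone, adjusted p = 0.057), and fatty acid oxidation 12 of 25 lower and 4 higher (13 and 4 adjusted over the list alone, adjusted p = 0.057). ATP synthase had 5 of 16 lower and 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.067), and complex I had 10 of 36 lower and 3 higher (10 and 3 adjusted over the list alone, adjusted p = 0.17), with Ndufb6 at -0.39. Of 4 tested glucose transporters, too few for camera, Slc2a3 rose and Slc2a9 was at 0.16 (adjusted p = 0.044), a call that ended without any 1 of 8 libraries, which were control replicates 2 to 4, guide 1 replicates 1 and 3 and guide 2 replicates 1, 2 and 4 (highest adjusted p = 0.13).

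**Figure D2:**
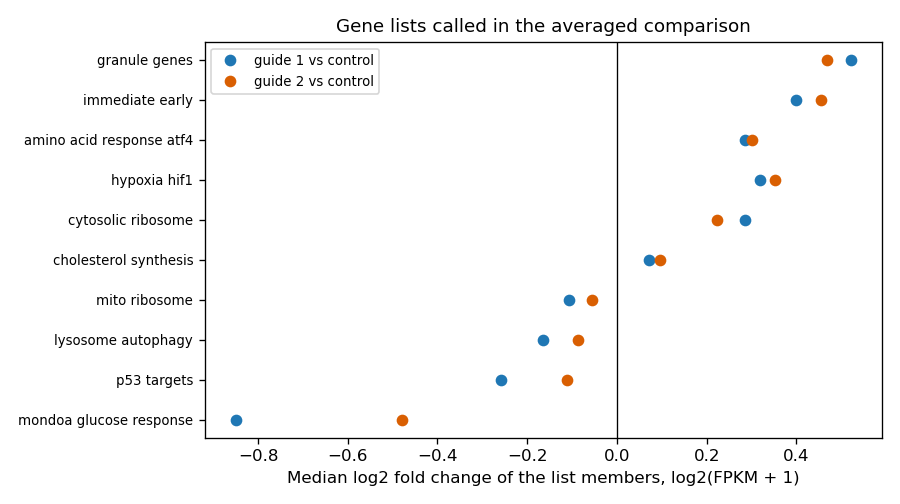
Median log2 change of the tested members of each list called for both guides averaged, on a log2 scale, with 1 point per guide against control. For each of these 10 lists both guides lie on the same side of 0.

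Guide 1 against control asked what the first guide changed. The largest increases were Camp (3.64), Ngp (2.53), Tmem119 (2.49), Slc2a3 (2.43) and Fcnb (2.38), as log2 changes, and the largest decreases were Mir142b, Gstt1 (-2.98), Wfdc15a (-2.30), Btla (-2.25) and Hpgd (-2.21). Mir142b was listed at 0 in all 4 guide 1 libraries, so no fold is given, and its call ended without control replicate 1, 2 or 4 (highest adjusted p = 0.058). Kit rose by 2.13 and Cdkn1a fell by 0.58 (adjusted p = 0.0057). In all, 2090 genes were higher and 2325 lower, 106 and 89 of them at least 2-fold in FPKM + 1.

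Camera called 15 lists for guide 1, 5 higher and 10 lower. The higher ones were the amino acid, hypoxia, ribosomal, immediate-early and granule lists described above. The 4 lists that fell for both guides averaged were again lower. Among the other lower ones, TCA cycle genes had 13 of 31 lower and 2 higher (13 and 2 adjusted over the list alone, adjusted p = 0.032) and complex I 13 of 36 lower and 2 higher (14 and 2 adjusted over the list alone, adjusted p = 0.043). ATP synthase genes had 7 of 16 lower and 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.038) and fatty acid oxidation 14 of 25 lower and 3 higher (14 and 3 adjusted over the list alone, adjusted p = 0.014). Guide 1 replicate 1 was lowest for complex I, with a mean log2 value of 6.26 against 6.39 to 6.48 in replicates 2 to 4 and 6.44 to 6.53 in control. For ATP synthase these values were 7.505, 7.67 to 7.78 and 7.76 to 7.84. Guide 1 replicate 3 lay inside the control range for both lists. Monocyte and macrophage genes had 19 of 44 lower and 6 higher (20 and 7 adjusted over the list alone, adjusted p = 0.014), and interferon-response genes 15 of 38 lower and 4 higher (16 and 4 adjusted over the list alone, adjusted p = 0.046). With an estimated correlation the 15 lists had adjusted p = 0.55 to 0.70, and complex I had adjusted p = 0.077 with quantile normalization. The mean log2 value of the monocyte and macrophage list was 5.43 and 5.31 in control replicates 1 and 2 and 5.05 and 5.01 in control replicates 3 and 4.

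Guide 2 against control asked the same for the other guide. The largest increases were Camp (2.52), Pdpn (2.36), Ccl2 (2.03), Il7r (1.98) and Fcnb (1.97), and the largest decreases Gstt1 (-2.41), Arrdc4 (-1.72), Hpgd (-1.64), Txnip (-1.50) and Btla (-1.47), as log2 changes. Pdpn, Ccl2 and Il7r were high in guide 2 replicates 1 to 3 and near guide 1 in replicate 4: Ccl2, a monocyte-attracting chemokine, had 5.85 FPKM there against 41.8 ± 24.98 for the group (SD, n = 4). The Ccl2 call ended without control replicate 3 or 4 or guide 2 replicate 1, 2 or 3 (highest adjusted p = 0.061). Over every library left out in turn its log2 change ran from 1.71 to 2.78. In all, 1455 genes were higher and 1470 lower, 73 and 19 of them at least 2-fold in FPKM + 1. Camera called 11 lists, 9 higher and 2 lower. Not called for both guides averaged were unfolded protein response genes of the endoplasmic reticulum, with 10 of 27 higher and 0 lower (13 and 0 adjusted over the list alone, adjusted p = 0.00018), and G1/S genes with 26 of 60 lower and 0 higher (27 and 0 adjusted over the list alone, adjusted p = 1.7e-05). Guide 2 replicate 4 lay apart here too: the mean log2 value of the unfolded protein response list was 6.26 there, 6.47 to 6.60 in replicates 1 to 3 and 6.20 to 6.22 in control, and that of the G1/S list was 5.10, 4.93 to 4.97 and 5.09 to 5.15. Also called here and not for both guides averaged were glycolysis with 6 of 25 higher and 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.027) and glycogen with 6 of 16 higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.045). With an estimated correlation the 11 lists had adjusted p = 0.26 to 0.63, and glycolysis had adjusted p = 0.14 with quantile normalization.

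Genes called with both guides in the same direction numbered 1146 higher and 1103 lower, and 0 were called in opposite directions by limma. Slc2a3, Txnip, Arrdc4, Kit, Camp and Mpo were among them. Independent lists of these sizes would share 286 and 321. In 100 simulated draws with no effect and the same shared controls at most 0 and 0 were shared, which says little, since limma calls few genes where nothing changes. The log2 changes of the guides correlated at 0.707 across genes against a simulated 0.499, with a covariance of 0.0774 against 0.013, a difference of 0.0645. With the control libraries split so that the guides shared none, 558 to 868 genes were shared higher and 453 to 791 lower, with 0 to 27 opposite.

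Guide 2 against guide 1 tested the difference between guides directly. Monocyte and macrophage genes were higher with guide 2: Clec4n, a C-type lectin receptor, had 12.4 ± 1.07 FPKM with guide 1 and 79.9 ± 44.7 with guide 2 (SD, n = 4), a log2 difference of 2.24, and Msr1, a scavenger receptor, had 5.29 ± 1.17 and 26.3 ± 14.3. Wfdc17 (2.10), Fabp4 (1.92) and Pdpn (1.84) were the other largest increases, and Hotairm1 (-1.25), Camp (-1.12), Tmem119 (-1.04), Cdkn1c (-1.04) and Myl10 (-0.99) the largest decreases. Clec4n stood at 13.6 FPKM and Msr1 at 5.06 in guide 2 replicate 4. In control these 2 genes had 25.6 ± 11.1 and 8.01 ± 3.26 FPKM (SD, n = 4). The calls of all 10 genes ended without 1 of 4 to 10 libraries, among them guide 1 replicates 2 and 4 and guide 2 replicates 2 and 3 for each gene (highest adjusted p = 0.065 for Tmem119 to 0.14 for Fabp4). Of the 44 monocyte and macrophage genes 22 were higher and 0 lower (31 and 1 adjusted over the list alone, camera adjusted p = 1.3e-09). Against control this list was not called with guide 2 (10 higher and 5 lower, camera adjusted p = 0.20), and it was lower with guide 1. Its mean log2 value was 4.80 in guide 2 replicate 4 and 5.61 to 5.70 in guide 2 replicates 1 to 3. With guide 1 it was 4.70 to 4.82, and in control 5.01 to 5.43. Of 60 G1/S genes 17 were lower and 0 higher (43 and 0 adjusted over the list alone, adjusted p = 4.1e-14). Of 27 unfolded protein response genes 4 were higher and 0 lower (17 and 0 adjusted over the list alone, adjusted p = 8e-07), and of 31 p53 targets 7 were higher and 0 lower (14 and 1 adjusted over the list alone, adjusted p = 0.00022). In guide 2 replicate 4 the mean log2 value of the G1/S list was 5.10 (5.14 to 5.19 with guide 1), that of the unfolded protein response list 6.26 (6.22 to 6.32 with guide 1) and that of the p53 targets 3.64 (3.53 to 3.63 with guide 1 and 3.79 to 3.88 in guide 2 replicates 1 to 3). All 12 lists called were lost with an estimated correlation (adjusted p = 0.61 to 0.91).

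Between the guides, 3174 genes had an unadjusted limma p under 0.05. After adjustment 552 genes were higher and 416 lower with guide 2 than with guide 1, 56 and 4 of them at least 2-fold in FPKM + 1. This total of 968 depended on single libraries: limma called 0 genes without guide 1 replicate 2, guide 1 replicate 4 or guide 2 replicate 3 (2570, 2588 and 2394 at an unadjusted p under 0.05), 1 without guide 2 replicate 2, 123 without guide 2 replicate 1, 250 without guide 1 replicate 1 and 2678 without guide 2 replicate 4.

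**Figure D3:**
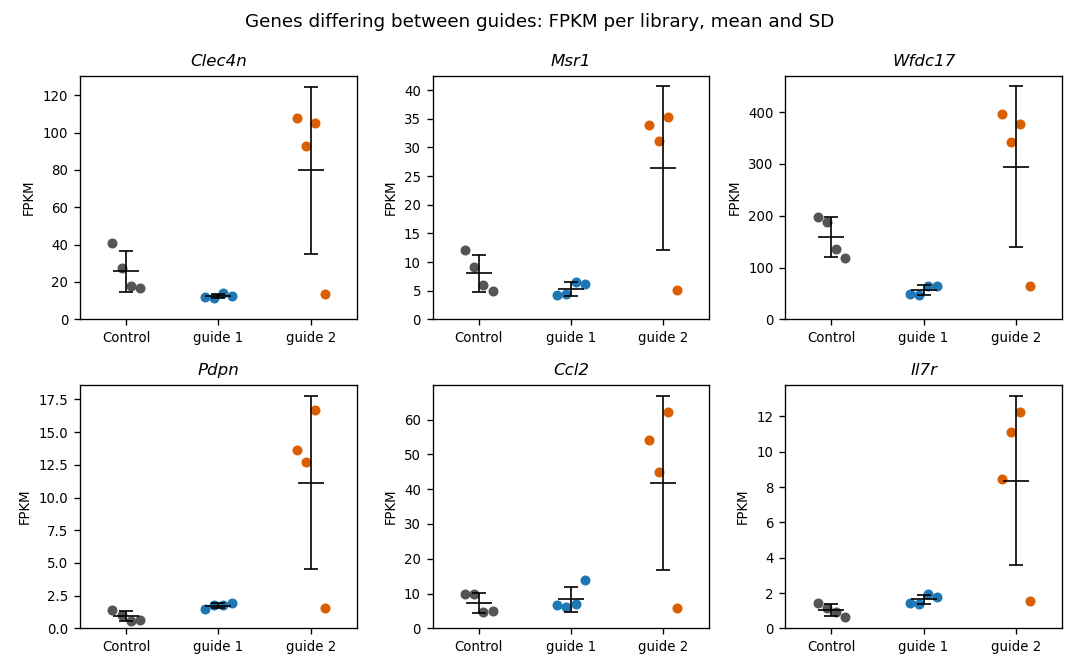
FPKM per library for 6 genes with large guide 2 differences, with replicates 1 to 4 of each group from left to right and the mean and SD as bars, on axes that start at 0. Guide 2 replicates 1 to 3 lie above the other libraries, and guide 2 replicate 4 lies near guide 1, at 13.6 FPKM for Clec4n and 5.06 FPKM for Msr1.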

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

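The tests of a mislabelled sample, of a difference shared with the controls and of mixed-in macrophages were chosen only after the result was seen, while the splits of the samples and the tests of the ribosomal genes were planned before their results.

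Over 2800 genes that tell guide 2 replicates 1 to 3 from guide 1, the median relative position of guide 2 replicate 4 was 0.182 (0 is guide 1 and 1 is guide 2), inside the range of held-out guide 1 libraries (-0.0113 to 0.218) and away from the other guide 2 libraries (0.787 to 0.991). That alone would fit a mislabelled guide 1 library, but a mislabelled sample cannot be told apart, since in a test added after this value was seen the library showed 0.781 to 0.823 of the guide 1 response (median over genes called between control and 3 guide 1 libraries), below held-out guide 1 libraries (0.868 to 1.04) by less than their range and above the other guide 2 libraries (0.468 to 0.598). Of the 33 named genes called between guides, with this library counted as guide 2, it lay beyond all 4 guide 1 libraries on the guide 2 side in 23, and against 3 guide 1 libraries in 23 to 27, where the held-out ones did so in 2 to 18. Calling the genes with these labels favours that outcome, so no conclusion on the label is drawn from these counts. A library difference shared with the controls cannot be told apart, since its correlation across genes was 0.364 and the highest other pair gave 0.378, and an effect of guide 2 itself stays open and untested, since the guide is the group. Macrophages mixed into replicates 1 to 3 cannot be told apart either: 84.1% of 44 tested monocyte and macrophage genes, all expressed in these libraries, were higher in guide 2, with Lyz2 at 1420 FPKM in replicates 1 to 3 and 644 in replicate 4 against 652 with guide 1, but Ly6c2 at 918 and 1050 against 1090, although the sort for GFP should remove cells that were not transduced.

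The rise of the cytosolic ribosomal protein genes was weighed against 2 technical explanations. The tables argue against a transcript length bias, since the list's median of 0.25 stood above all 10000 lists matched on length and expression (percentile 100, highest 0.14), with a length for 79 of 79 members. The normalization of the deposited FPKM stays open as part of it. FPKM totals were higher in every guide library (643432 to 737648) than in control (590561 to 643260), and how this relates to the rise was not tested. With quantile normalization 24 of the 59 members called higher remained so, with a list median of 0.09 and a camera adjusted p of 0.00089. That loss cannot decide it, since the method gives every library the same distribution and so can shrink a real rise of abundant genes. The mean log2 value of this list, 9.73 to 10.16 per library, was the highest of the lists. With median-ratio scaling, whose factors of 0.998 to 1.02 change little, all 59 remained and the median was 0.26. An effect of the guides on these genes stays open.

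Other splits of the samples were counted for each result. For both guides averaged the real split gave 4255 genes and the highest of the other splits 2073, and 1 of 100 splits was as large, the real one. For guide 1 these were 4415 and 1, for guide 2 they were 2925 and 268, and for guide 2 against guide 1 they were 968 and 716. In each, 1 of 35 splits was as large, the real one, which is the smallest share possible there. No other split counted gave as many genes. The splits cannot exclude a chance difference between cultures, since the labels do not say that replicates are separate cultures. The split with 716 genes exchanged guide 1 replicate 3 with guide 2 replicate 4, which points to a structure of the samples. The shared genes numbered 2249 against 4 in the highest other split, with 1 of 100 as large. Chance cannot be excluded for the number of list calls: 62 of 100 splits gave at least the 10 lists of both guides averaged (highest other 19), 12 of 35 the 15 lists of guide 1 (19), 19 of 35 the 11 lists of guide 2 (18) and 14 of 35 the 12 lists of guide 2 against guide 1 (17).

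A sample far from the rest of its group was found in 19 of 324 groups of 4 examined. Chance gives about 1 in 20 for independent groups, which these are not. Pdpn, Ccl2, Clec4n, Wfdc17, Fabp4, Msr1 and Myl10 were named for large guide 2 differences. Clec4n and Msr1 are also in the monocyte and macrophage list. Flags of these genes are therefore not separate evidence. Of the 19 flags, 9 were for guide 2 replicate 4. In that library Pdpn had 1.57, Ccl2 5.85, Clec4n 13.6, Wfdc17 65.3, Fabp4 1.14, Msr1 5.06 and Cd80 1.85 FPKM, each low, Myl10 had 15.9 FPKM, high, and the mean log2 value of the monocyte and macrophage list was 4.80, low. Hpgd had 1450 FPKM in control replicate 3, high, and Hotairm1 had 2.86 FPKM in control replicate 1, high. Mir142b was listed at 0 in control replicate 3 and at 73.9 FPKM in guide 2 replicate 2. Ccl2 had 13.8 FPKM in guide 1 replicate 4, Ddit4 had 8.54 FPKM in control replicate 4 and Atp6v0d1 had 92.0 FPKM in guide 2 replicate 1, each high. The mean log2 value was high for the amino acid response list in guide 1 replicate 3 (4.97), for the TCA cycle list in guide 2 replicate 1 (5.26) and for the unfolded protein response list in control replicate 3 (6.22).

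The test of guide 2 against guide 1 called 968 of the 10635 genes tested and 33 of the 85 named genes. The naming rule takes the largest called differences, so the higher share among named genes is no separate result. As log2 differences, those higher with guide 2 were Slc2a1 (0.67), Hpgd (0.56), Btla (0.78), Wfdc15a (1.02), Prdx4 (0.92), Slc18a1 (0.84), Tespa1 (0.50), P2rx7 (0.71), Ms4a6b (0.69), Glra3 (0.58), Pdpn (1.84), Il7r (1.59), Clec4n (2.24), Wfdc17 (2.10), Fabp4 (1.92), Msr1 (1.85), Mrpl16 (0.19), Arrdc3 (0.86), Cd80 (0.62) and Ndufb6 (0.28). Those lower with guide 2 were Camp (-1.12), Slc2a3 (-0.54), Ngp (-0.97), Tmem119 (-1.04), Chil1 (-0.92), Ltf (-0.78), Penk (-0.46), Txnip (-0.17), Hotairm1 (-1.25), Cdkn1c (-1.04), Myl10 (-0.99), Ddit4 (-0.46) and Kit (-0.88). The median log2 difference of the 12 lists called was 0.073 for complex I, 0.074 for mitochondrial ribosomal proteins, 0.11 for fatty acid oxidation, 0.22 for the unfolded protein response, 0.10 for lysosome and autophagy, 0.17 for p53 targets, -0.19 for G1/S, 0.092 for NRF2 targets, 0.094 for the interferon response, -0.16 for granule genes, 0.62 for monocyte and macrophage genes and 0.35 for megakaryocyte genes.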

How the results depend on the processing

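The covariate was chosen after seeing the data and computed from the same expression values, so it lowers the control spread by construction and no conclusion rests on it, while the other alternatives were planned. Of 456 alternative values of the counts, Slc2a1 changes and list calls, 397 kept their direction and side of the threshold (counts within 1.5 times), and of 2383 values of named genes 2261 did and 120 lost their call. The counts against control did so under each alternative but the fold minimum: the replicate block gave 1933 higher and 2064 lower for both guides averaged, and leaving out 1 library gave totals of 3514 to 4511, of 3730 to 4800 for guide 1 and of 2236 to 3166 for guide 2. No pairing by replicate number was seen, as the best match shared its number in 2 of 24 cases. This does not exclude a shared culture or day, on which the labels are silent. A fold minimum of 2 in FPKM + 1 passes fewer genes by construction. It left 76 and 38 genes for both guides averaged and 106 and 89 for guide 1. For guide 2 it left 73 and 19, and between guides 56 and 4. For the changes below the cause was not tested unless the construction shows it. Between guides, no filter gave 184 higher and 189 lower, array weights 1976 and 1860, only the 2 groups compared 165 and 164, and the covariate 109 and 102, of which 185 were among the 968. Leaving out 1 library gave 0 to 1441 higher and 0 to 1237 lower, with the highest without guide 2 replicate 4 and limma calls of 0 without guide 1 replicate 2 or 4 or guide 2 replicate 3, where 2570, 2588 and 2394 genes had an unadjusted p under 0.05. Slc2a1 differed between guides by 0.67 with no filter (adjusted p = 0.064), by 0.44 with the covariate (adjusted p = 0.052) and by 0.59 to 0.78 with 1 library left out (adjusted p = 0.0036 to 0.093). Its change with 1 library left out was -0.349 to -0.085 for both guides averaged, -0.68 to -0.42 for guide 1 and -0.015 to 0.262 for guide 2, reversed without control replicate 3. Itgam ran from -0.006 (without control replicate 3, reversed) to 0.067, never called. List calls fell to 0 for both guides averaged, 0 for guide 1, 0 for guide 2 and 0 between guides with camera's estimated correlation, against 10, 15, 11 and 12. With no filter 18 lists were called for both guides averaged, the covariate gave 10, 12, 10 and 16 lists with 18 calls lost or gained, and fry, which does not compare a list with other genes, called 22 and 25 for both guides averaged and guide 1. With split controls, which leave 2 control libraries per guide, the shared genes numbered 868 and 791, 711 and 577, 558 and 453, 693 and 509, 626 and 504, and 613 and 477, in place of 1146 and 1103. The depth is not recorded, and a depth relative to control replicate 1, estimated from steps between low FPKM values, ran from 0.667 (guide 1 replicate 3) to 3.08 (control replicate 4). Only 48.4% to 64.4% of the low ratios lay within 0.03 on the log2 scale of a quotient of small whole numbers, so this estimate was not used and what depth limits cannot be stated.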

Other observations

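The neutrophil test was chosen only after the result was seen, and the genes named in the next 2 paragraphs outside the rule were chosen after their values were seen.

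Genes of the MLL-fusion self-renewal program moved both ways, and the list was not called for both guides averaged, with 11 of 27 lower and 3 higher (adjusted p = 0.12). Id2, an inhibitor of helix-loop-helix transcription factors, had a log2 change of 1.27, while Tcf4 was at -0.71 and Lmo2, a hematopoietic transcription cofactor, at -0.41, each called. Among 17 progenitor genes, 6 were higher and 5 lower (adjusted p = 0.51): Kit rose, and Cd34, a surface marker of progenitors, was at -1.10 (adjusted p = 8.4e-05). Derl3, an endoplasmic reticulum degradation gene, was at 1.90 and Ddit3, a transcription factor of the stress response, at 1.22.

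Markers of other cell types that the sort could hold were not called as lists for both guides averaged. T and NK cell genes had 3 of 5 higher and 0 lower (Nkg7 1.43, Il7r 1.19 and Cd28 0.62; adjusted p = 0.15), stroma and endothelium 2 of 7 higher and 3 lower (adjusted p = 0.17), mast cells, basophils and eosinophils 2 of 11 higher and 2 lower (adjusted p = 0.88), the erythroid list 1 of 5 higher (adjusted p = 0.95) and megakaryocytes 0 of 5 (adjusted p = 0.34). B cells had 2 tested genes, too few for a test.

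Granule genes rose with Kit, and mature neutrophils mixed into the guide libraries may account for the granule part. Of 24 mature neutrophil genes, 23 were tested, and 47.8% (11) were called higher and 4 lower, so the explanation cannot be told apart from a change in the leukemia cells. The outcome turns on 1 gene: the first criterion, under 50% called with a low median log2 change (0.177 here), would have argued against neutrophils. A binomial bound on that share was required after the value was seen. Of the 24 genes 11 are also in the granule list, and the most abundant, Slpi, went from 550 FPKM in control to 458 in the guide libraries, while Wfdc21 went from 344 to 441. The sort for GFP should remove such cells unless they were transduced.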
